A study of Mus musculus with 4 samples.

How the data were processed

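RNA-seq was carried out on CD4+CD25+ cells sorted from the spleens of 7-week-old mice, 2 samples of wild-type (WT) genotype and 2 of Helios knockout (KO) genotype. Helios is the zinc finger transcription factor encoded by Ikzf2, and CD4+CD25+ is the surface phenotype used to sort regulatory T cells (Tregs). Groups and replicate numbers were taken from the sample titles and genotype labels. Per the labels' protocols, full-length cDNA was made from 5 ng of total RNA with a SMART-Seq low-input kit and 10 PCR cycles, and libraries were made by Tn5 tagmentation with 12 further cycles. That preparation does not mark strand, so reads of overlapping antisense genes cannot be separated. Per the submitters' processing notes, bcl2fastq 2.17.1.14 was used and the genome build was mm10. The aligner and the read counter are not given in the sources used here.

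The deposited signal values are, per the file headers, read counts normalised by the authors and divided by the median transcript length in kb. Such a value is a normalised read number per kb of transcript, not scaled to a common total of reads, and 1 read is worth a different value in each gene. The table analysed here holds 16383 genes in the order of their Ensembl identifiers. All 16383 matched the GENCODE M21 annotation of the GRCm38 assembly (the same assembly as mm10), which supplied coordinates and transcript lengths. Of the 21951 protein-coding genes in that annotation, 4425 (20.2%) have identifiers after the last one in the table and were not analysed here.

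The test had been planned for raw read counts. Because the values are normalised and scaled by length, a count model was not used as the main test, and limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) in its place. Genes with a value of at least 10 in at least 2 of the 4 libraries were kept. Genotype was the only term, variances were moderated with a trend on the mean and with robust estimation, tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Means are given ± SD of the 2 libraries of a group. The labels do not say that the samples came from separate mice, so p-values measure only the spread between these samples, which may be partly technical.

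Read numbers behind the values were recovered by comparing low genes between libraries and multiplying by transcript length. With a tolerance of 0.01 read, 97.2% of the 58026 nonzero values came out whole. Recovered reads over the genes of the table numbered 52466462 for WT replicate 1, 50870870 for WT replicate 2, 42090057 for Helios KO replicate 1 and 48975294 for Helios KO replicate 2. They were used for depth, for CPM and for an alternative fit with limma-voom. Over the genes of a group, the chi-square per degree of freedom of the recovered reads was 37.0 for the WT pair and 124 for the knockout pair, far above the value of sampling noise alone, so no library was treated as a copy of another.

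Before the data were examined, 32 gene lists were fixed for Treg, T helper, signalling, metabolic and quality programmes and for other cell types of the spleen. Ikzf2 was left out of every list. The 30 lists with at least 4 tested members were tested with camera in limma at a preset correlation of 0.01 and adjusted over lists, and camera with an estimated correlation and fry were run beside it. The sex-linked list served as a check and was not tested, and the innate-like T cell list had too few members. Of the 6 sex-linked genes only Kdm5d was in the table, so the check rested on that gene. The genes named were also set by a rule fixed at that time. They are Ikzf2, the 10 largest changes per direction among called genes (or, with fewer, the 5 with the smallest p), the called members of each list (or, with none, the 2 with the smallest p), and Foxp3, Il2ra, Cd4, Ctla4, Ikzf1, Ikzf3 and Ikzf4. Predicted genes, pseudogenes and antigen receptor segments were left out of the ranking by p. The rule named 72 genes, and any gene chosen after its values were seen is marked as such.

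Alternatives changed 1 choice at a time. They covered rescaling to median ratios or to recovered read totals, no low-value filter, a mean of at least 10 CPM, limma-voom, the replicate number as a block, leaving out each library, leaving out antigen receptor, haemoglobin and sex-linked genes, a pseudocount of 0.1, and a threshold of 1 on the absolute log2 fold change. Library quality weights and a fit without the variance trend were added after the data were seen.

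The fit was tested on simulated data in 20 draws over a median of 11419 genes, with the spread of each gene as between the 4 libraries. It recovered 71.8% of 2-fold changes and 90.9% of 4-fold changes, and 12.3% of its calls were false. With the spread of each gene as between the 2 WT libraries it recovered 90.6% of 2-fold changes and 7.98% of calls were false, and with a spread set by the trend on the mean alone 6.56% of calls were false. In all 3 settings the share of false calls was above the threshold of 0.05 on the adjusted p. A simulated list of 20 genes shifted by 0.80 on the log2 scale had an unadjusted camera p under 0.05 in 20 of 20 draws. Each draw held 100 genes changed 2-fold and 100 changed 4-fold, so the recovery above need not hold where few genes change. Simulated genes varied independently and with the same spread in all 4 libraries. Neither lists whose members move together nor an outlying library was therefore covered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.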

Results

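The transcriptomes of splenic CD4+CD25+ T cells were compared between WT mice and mice lacking Helios, to ask which genes of Tregs depend on this transcription factor. Each genotype had 2 libraries. The 4 libraries held 42090057 to 52466462 recovered reads, and 11571 genes were expressed highly enough to be tested. Values are normalised reads per kb of median transcript length.

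Ikzf2 itself (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245, minus strand, mm10) was measured first. Its value was 5282 and 7864 in the WT libraries and 4396 and 3104 in the knockout libraries. The mean was 6573 ± 1826 in WT (SD, n = 2) and 3750 ± 914 in the knockout (SD, n = 2), a ratio of 0.571. Both knockout libraries lay below both WT libraries, with a log2 fold change of -0.80 (SE 0.28). The difference did not pass the test over all genes, with an adjusted p of 1.00 in limma. Leaving out Helios KO replicate 1 gave a log2 fold change of -1.05, and leaving out Helios KO replicate 2 gave -0.55. Helios KO replicate 2 is the library with transcripts of other blood cells, described below. Foxp3 (-0.49) and Il2ra (-0.56) also lay below the WT mean there, but not in replicate 1 (0.22 and 0.033). Cd4 (-0.090) and the median of the T cell identity list (-0.06) lay close to the WT mean in replicate 2. The labels do not say which exons the null allele lacks, so reads from the remaining exons do not contradict the genotype, and a value over the whole gene is a weak check of it.

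The values of Foxp3, Il2ra and Ctla4 overlapped between the genotypes, and the genes with the smallest p were Actg2, lower in the knockout, and Scin, higher in it. Foxp3, the lineage-defining transcription factor of Tregs, had values of 37578 and 33448 in WT and 41264 and 25224 in the knockout (log2 fold change -0.14, SE 0.26). Scin, which encodes the actin-severing protein scinderin, was at 93.5 and 88.8 in WT and at 400 and 409 in the knockout, a ratio of 4.44. Actg2, a smooth muscle actin gene, was at 660 and 672 in WT and 176 and 205 in the knockout, a ratio of 0.286. Neither of these genes, nor any other, passed the threshold over all genes.

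With predicted genes, pseudogenes and antigen receptor segments left aside, the 5 genes with the smallest p among those higher in both knockout libraries were Scin, Slc43a1, Dipk1c, Cd9 and Il10ra. The predicted gene Gm973, left aside by that rule, had an unadjusted limma p of 0.000111 and a log2 fold change of 2.74. Scin (ENSMUSG00000002565, chromosome 12, 40059769 to 40134228) had a log2 fold change of 2.14 (SE 0.20). Slc43a1, a transporter of large neutral amino acids (ENSMUSG00000027075, chromosome 2, 84838850 to 84863594), averaged 299 ± 22.2 in WT and 851 ± 145 in the knockout (SD, n = 2 each), a log2 fold change of 1.50 (SE 0.18). Dipk1c (ENSMUSG00000047992, chromosome 18, 84719236 to 84740436) averaged 115 ± 4.88 and 360 ± 2.76, a log2 fold change of 1.64 (SE 0.20). Cd9, a tetraspanin of the cell surface (ENSMUSG00000030342, chromosome 6, 125460266 to 125494791), averaged 3236 ± 162 and 5286 ± 44.1, a log2 fold change of 0.71 (SE 0.09). Il10ra, a chain of the interleukin 10 receptor (ENSMUSG00000032089, chromosome 9, 45253837 to 45269149), averaged 3323 ± 242 and 5476 ± 78.2, a log2 fold change of 0.72 (SE 0.10).

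By the same rule, the 5 genes with the smallest p among those lower in both knockout libraries were Actg2, Ptpn5, Eno2, Ptpn4 and Atp6v0d2. Actg2 (ENSMUSG00000059430, chromosome 6, 83512905 to 83536265) had a log2 fold change of -1.80 (SE 0.17), and its value is uncertain because actin genes are near-identical over long stretches and the handling of shared reads is not given. Ptpn5, a tyrosine phosphatase (ENSMUSG00000030854, chromosome 7, 47077795 to 47133684), averaged 1931 ± 195 in WT and 905 ± 19.1 in the knockout (SD, n = 2 each), a log2 fold change of -1.09 (SE 0.12). Ptpn4, another tyrosine phosphatase (ENSMUSG00000026384, chromosome 1, 119652467 to 119837613), averaged 3273 ± 314 and 1702 ± 107, a log2 fold change of -0.94 (SE 0.12). Eno2, the neuronal form of the glycolytic enzyme enolase (ENSMUSG00000004267, chromosome 6, 124760053 to 124769673), averaged 907 ± 22.8 and 431 ± 12.3, a log2 fold change of -1.07 (SE 0.13). Atp6v0d2, a subunit of the vacuolar proton pump (ENSMUSG00000028238, chromosome 4, 19876841 to 19922605), averaged 396 ± 14.6 and 108 ± 23.6, a log2 fold change of -1.88 (SE 0.24). The adjusted p of these 10 genes lay between 0.427 and 0.453 in limma.

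**Figure D1:**
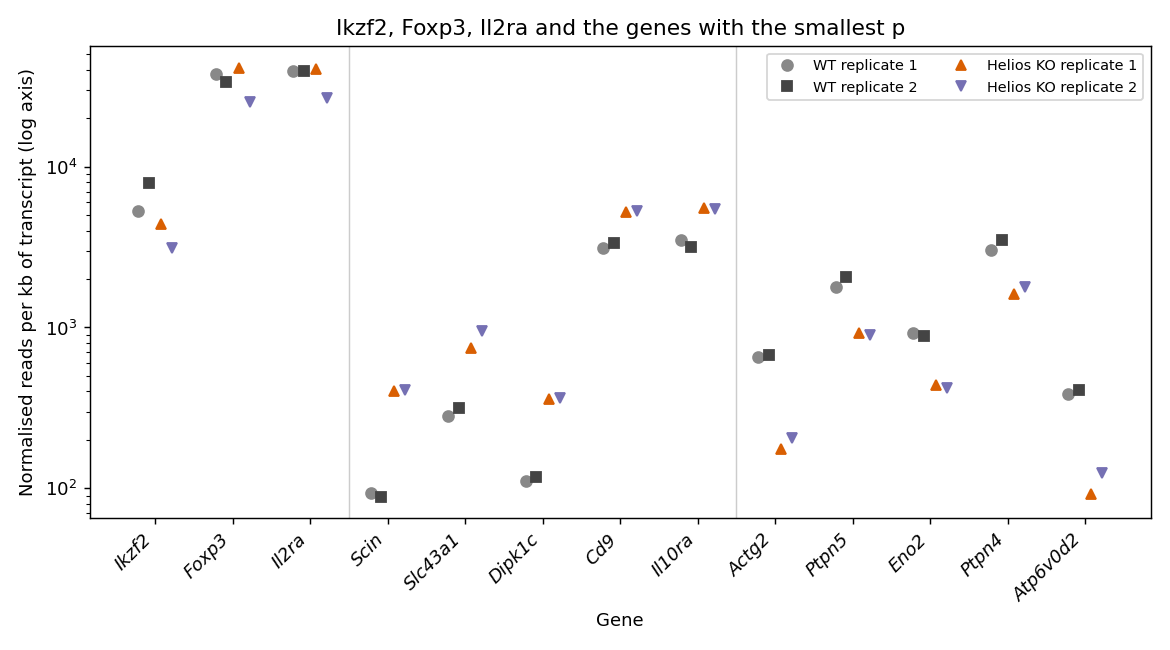
Normalised reads per kb of transcript (log axis) of Ikzf2, Foxp3, Il2ra and the 5 genes with the smallest p in each direction, 1 point per library (2 WT and 2 Helios KO). Predicted genes, pseudogenes and antigen receptor segments were left out of the ranking. Both knockout points of Scin, at 400 and 409, lie above both WT points, and the Foxp3 points of the genotypes overlap.

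In limma, 0 of 11571 genes were called changed. At an unadjusted p under 0.05 there were 386 genes, 148 higher and 238 lower in the knockout, where 579 would be expected by chance, and limma-voom gave 0 called genes and 383 at that unadjusted p. Leaving out Helios KO replicate 2 gave 40 called genes (8 higher, 32 lower) and leaving out Helios KO replicate 1 gave 758 (694 higher, 64 lower), each with a lone knockout library assumed to vary like the WT libraries. The knockout libraries differed from each other by at least 2-fold in 1252 genes and the WT libraries in 411. Helios KO replicate 2, the lone knockout library behind the larger count of called genes, held the transcripts of other blood cells described below. Among tested genes, 432 lay at least 4-fold above all other libraries there.

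In the core Treg list, 20 of 24 tested members overlapped between the genotypes and 4 lay lower in both knockout libraries. None passed the test over all genes, and 1, Itgae, was called when adjusted over the list alone. Itgae, the integrin alpha chain CD103 that binds E-cadherin (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446), averaged 2092 ± 168 in WT and 1274 ± 23.1 in the knockout (SD, n = 2 each), a log2 fold change of -0.71 (SE 0.11). Cd83 was at 8566 and 9305 in WT and at 5329 and 7500 in the knockout. Il2ra, the interleukin 2 receptor alpha chain used for the sort, had a log2 fold change of -0.27 (SE 0.21), with 40457 in Helios KO replicate 1 and 26759 in replicate 2. Ctla4, an inhibitory receptor, had 0.13 (SE 0.19) and Cd4 had 0.03 (SE 0.12). Without Helios KO replicate 2 the log2 fold change was 0.22 for Foxp3 and 0.033 for Il2ra, and without Helios KO replicate 1 it was -0.15 for Ctla4 and -0.090 for Cd4. The list as a whole was not called (camera adjusted p = 0.123), but without Helios KO replicate 1 it was called lower (adjusted p = 0.000286), and without Helios KO replicate 2 it was not called (adjusted p = 0.193). Its median difference from WT was -0.16 in Helios KO replicate 2 and 0.08 in replicate 1. In replicate 2, 71 tested members of 6 lists of other blood cells had a median of 3.79, with Bst2 of the interferon list left out. The T cell identity list had a median of -0.06 in that library.

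Effector Treg genes lay on both sides. Of 21 tested members, 6 lay higher and 1 lower in both knockout libraries, 0 passed the test over all genes and 1, Il1rl1, was called when adjusted over the list alone. Il1rl1, the interleukin 33 receptor ST2 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), averaged 1183 ± 139 in WT and 581 ± 10.6 in the knockout, a log2 fold change of -1.02 (SE 0.14). Il10, which encodes an anti-inflammatory cytokine, averaged 146 ± 51.2 and 358 ± 16.5, a log2 fold change of 1.33 (SE 0.29). Il1rl1, Il10 and Ptpn4 lie on chromosome 1, as does Ikzf2. The camera adjusted p of this list was 0.0610. Among central and naive T cell genes, 0 of 19 members passed and the list was not called (camera adjusted p = 0.248), with Igfbp4 at a log2 fold change of 0.99 (SE 0.18) and Id3 at -0.66 (SE 0.15).

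Among T helper programmes, receptors and regulators of type 2 and type 17 responses included members on both sides. Of 9 Th2 genes 0 passed over all genes and 3 were called when adjusted over the list alone, and the list was not called (camera adjusted p = 0.851). Of 12 Th17 genes 0 passed over all genes and 2 were called when adjusted over the list alone. These were Ccr6, a chemokine receptor, at 3188 ± 222 in WT and 2107 ± 149 in the knockout (SD, n = 2 each), with a log2 fold change of -0.60 (SE 0.11), and Rora, a nuclear receptor, at -0.73 (SE 0.16). The Th17 list had a camera adjusted p of 0.0583, with a median difference from WT of -0.98 in Helios KO replicate 1 and 0.40 in replicate 2. It was called lower without Helios KO replicate 2 (adjusted p = 3.86e-09), and without Helios KO replicate 1 it was not called (adjusted p = 0.631). Of 14 follicular helper genes 0 passed over all genes or over the list alone (camera adjusted p = 0.954). P2rx7, an ATP-gated channel, had a log2 fold change of -0.39 (SE 0.13) and Il4 had 1.89 (SE 0.51) at low values of 31.5 ± 14.0 and 119 ± 49.9. Th1 genes were called higher as a list (17 members, camera adjusted p = 0.00663), with an adjusted p of 0.702 with an estimated correlation. None of them passed alone over all genes or over the list, and their median difference from WT was -0.12 in Helios KO replicate 1 and 1.68 in replicate 2. Cxcr3, a chemokine receptor of Th1 cells, had a log2 fold change of 0.40 (SE 0.18) and Il18r1, an interleukin 18 receptor chain, had -1.48 (SE 0.40). Il18r1 also lies on chromosome 1 (40465552 to 40500854) and starts just past the end of Il1rl1.

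Camera with the preset correlation called 2 lists of T cell activation higher in the knockout, and neither call held with an estimated correlation. Of 14 conventional T cell activation genes, 8 lay higher in both knockout libraries and 0 lower, and camera called the list (adjusted p = 5.67e-06). Its adjusted p was 0.702 with an estimated correlation, where the unadjusted p was 0.0349. Tnfsf8, the CD30 ligand, averaged 1548 ± 156 in WT and 2334 ± 332 in the knockout, a log2 fold change of 0.59 (SE 0.14). Of 23 T cell receptor immediate early genes, 12 lay higher in both knockout libraries and 0 lower (camera adjusted p = 6.96e-08, and adjusted p = 0.702 with an estimated correlation). In that list 1 gene, Dusp2, was called when adjusted over the list alone. Dusp2, a nuclear phosphatase of MAP kinases (ENSMUSG00000027368, chromosome 2, 127336159 to 127338376), averaged 13486 ± 1863 and 22540 ± 1176, a log2 fold change of 0.75 (SE 0.13). Nfkbiz had 0.52 (SE 0.15). These 2 lists were the ones called higher with all libraries, without Helios KO replicate 1 and without Helios KO replicate 2 alike. The median difference from WT of the immediate early list was 0.10 in Helios KO replicate 1 and 1.12 in replicate 2. In replicate 2 the lists of other blood cells had medians of 1.72 to 8.01. The median of the conventional activation list was 0.35 in replicate 1 and 0.34 in replicate 2, but its members differed between the libraries. Named after their values were seen, Ifng was at 0.53 and 3.44, Pde3b at -0.39 and 2.62, and Lta, the other way, at 0.49 and -0.31. Junb, Nr4a1, Nr4a2 and Zfp36, named after their values were seen, lay below the WT mean in replicate 1, with differences of -0.10, -0.11, -1.07 and -0.18. Fos, an immediate early gene chosen after its values were seen, was at 26396 in Helios KO replicate 2 and at 679 to 820 in the other libraries. Of the conventional activation and immediate early lists, 0 members passed over all genes, and of the first 0 passed when adjusted over the list alone.

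Camera with the preset correlation called the interferon response list higher in the knockout (adjusted p = 4.94e-07), a call lost with an estimated correlation (adjusted p = 0.702) and with fry (adjusted p = 0.586). Of its 32 tested members, 18 lay higher and 1 lower in both knockout libraries, with a median difference from WT of 0.26 in Helios KO replicate 1 and 0.15 in replicate 2. No member passed over all genes or when adjusted over the list alone. Iigp1, an interferon-inducible GTPase, averaged 1632 ± 226 in WT and 3032 ± 805 in the knockout (SD, n = 2 each), a log2 fold change of 0.87 (SE 0.22), and Irgm1, of the same family, had 0.37 (SE 0.10). Without Helios KO replicate 1 the list was no longer called (camera adjusted p = 0.168).

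Of the other Ikaros family genes, 2 lay higher in both knockout libraries and 2 overlapped. Ikzf3, which encodes Aiolos, averaged 3895 ± 145 in WT and 5439 ± 616 in the knockout (SD, n = 2 each), a log2 fold change of 0.48 (SE 0.12), and was the 1 of 4 members called when adjusted over the list alone. Ikzf1, which encodes Ikaros, had 0.18 (SE 0.11), and Ikzf4, which encodes Eos, had -0.11 (SE 0.20), or 0.16 without Helios KO replicate 2. The list was not called (camera adjusted p = 0.0771), and 0 members passed over all genes.

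Among growth, energy and stress genes, camera with the preset correlation called 4 lists higher in the knockout, and none of these calls held with an estimated correlation or with fry. Nuclear genes of oxidative phosphorylation were called higher as a list (35 members, 16 higher and 0 lower in both knockout libraries, camera adjusted p = 1.13e-06), with an adjusted p of 0.702 with an estimated correlation, and a median log2 fold change of 0.12. The median difference from WT of this list was 0.11 in Helios KO replicate 1, where the list was called with that library as the only knockout (adjusted p = 0.000108), and 0.09 in replicate 2, where it was not (adjusted p = 0.168). Cox8a had 0.25 (SE 0.10) and Ndufa2 had 0.23 (SE 0.10). Cell cycle genes were called higher (37 members, camera adjusted p = 4.30e-05), with an adjusted p of 0.706 with an estimated correlation. The median log2 fold change of these genes was 0.20, and their median difference from WT was 0.02 in Helios KO replicate 1 and 0.36 in replicate 2, against 0.42 between the WT libraries, and without Helios KO replicate 2 the adjusted p was 0.417. Aurka, a mitotic kinase, had a log2 fold change of 0.50 (SE 0.22) and Mcm2, a replication helicase subunit, had 0.21 (SE 0.11). In these lists, and in the mitochondrial and heat shock lists, 0 members passed over all genes or over the list alone. Mitochondrial transcripts (8 members, camera adjusted p = 0.00145, adjusted p = 0.702 with an estimated correlation) had a median log2 fold change of 0.32, against 0.81 between the WT libraries, with mt-Co1 at 0.25 (SE 0.15) and mt-Nd1 at 0.49 (SE 0.28). Heat shock and stress genes (13 members, camera adjusted p = 0.00382, adjusted p = 0.702 with an estimated correlation) had a median of 0.19, against 0.37 between the WT libraries, with Dnajb1 at 0.48 (SE 0.17) and Hspb1 at -2.02 (SE 0.82). With Helios KO replicate 2 as the only knockout library, the mitochondrial list had a median difference from WT of 0.41 (adjusted p = 0.114) and the heat shock list 0.21 (adjusted p = 0.0574), so these calls ended without a smaller shift.

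Survival, checkpoint and metabolic lists were not called and held 0 members that passed over all genes. The camera adjusted p was 0.606 for apoptosis and survival (24 members), where the survival factor Bcl2l1 had a log2 fold change of -0.37 (SE 0.10) and the death receptor Fas had -0.28 (SE 0.10). It was 0.933 for the p53 response (17 members), with Sesn1 at -0.27 (SE 0.12), and 0.933 for costimulation and checkpoint receptors (19 members), with Tnfrsf25 at -0.36 (SE 0.13) and Tnfrsf9 at -0.33 (SE 0.13). It was 0.825 for chemokine receptors and trafficking (25 members), of which 2, Itgae and Ccr6, were called when adjusted over the list alone. It was 0.0775 for interleukin 2 and STAT5 targets (17 members), with Socs3 at 0.34 (SE 0.12) and Socs1 at 0.31 (SE 0.20). It was 0.268 for glycolysis (21 members), with the glucose transporter Slc2a3 at -0.34 (SE 0.09) and Gapdh at 0.15 (SE 0.09). It was 0.0867 for cholesterol synthesis (19 members), with Cyp51 at 0.25 (SE 0.18; -0.00402 without WT replicate 2) and Insig1 at 0.22 (SE 0.18). It was 0.114 for cytosolic ribosomal proteins (38 members), with Rps6 at 0.41 (SE 0.17) and Rplp1 at 0.20 (SE 0.09). Other than in the trafficking list, none of these members was called over its list alone.

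Transcripts of other blood cells were present in 1 library above the rest, Helios KO replicate 2. The neutrophil list (7 members) had a median difference from WT of 8.01 in that library and 1.33 in Helios KO replicate 1. The myeloid and dendritic list (21 members) had 4.60 and -0.57, the erythroid and platelet list (6 members) 4.41 and 0.01, the CD8 and natural killer list (17 members) 3.49 and -0.52, the B cell list (17 members) 2.69 and -0.22, and the plasma cell list (6 members) 1.72 and 0.08. T cell identity genes (13 members) had -0.06 and 0.12 and were not called (camera adjusted p = 0.205), with Cd6 at a log2 fold change of 0.32 (SE 0.16) and Cd247 at 0.15 (SE 0.12). The same library had the larger median difference from WT in the Th1, immediate early and cell cycle lists above and the lower one in the core Treg list.

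Camera called each of these 6 lists of other cells higher in the knockout, with adjusted p = 0.000134 for neutrophil, 1.88e-06 for myeloid and dendritic, 0.00382 for erythroid and platelet, 0.000300 for CD8 and natural killer, 0.000750 for B cell and 0.00316 for plasma cell genes. With an estimated correlation their adjusted p lay between 0.702 and 0.706, and 0 of their members passed over all genes or over the list alone. Without Helios KO replicate 2 the B cell, myeloid and natural killer lists turned lower in the knockout (adjusted p = 0.0119, 0.000572 and 4.54e-06), and the neutrophil, erythroid and plasma cell lists were not called (adjusted p = 0.112, 0.774 and 0.801). Single members showed the same spread, with Car2 at 377 and 405 in WT and 427 and 7245 in the knockout, Mmp9 at 731 and 550 against 811 and 2921, and Mzb1 at 7.67 and 6.37 against 12.5 and 141. Cd8a was at 20.2 and 17.6 against 19.4 and 69.2, Pax5 at 3.73 and 2.79 against 10.3 and 37.3, and Siglech at 11.5 and 1.56 against 11.6 and 137. Ppbp, Gzmk and Fcrla reached 275, 171 and 103 in Helios KO replicate 2, against 14.9, 30.2 and 11.7 in replicate 1. Cxcr2 lay above WT in both, at 0 and 31.6 in WT and 56.9 and 95.9 in the knockout. Bst2 had a log2 fold change of 0.24 (SE 0.11), with differences from WT of 0.35 in replicate 1 and 0.13 in replicate 2. Xbp1 had a log2 fold change of 0.35 (SE 0.10). The innate-like T cell list had 3 tested members and no list test, with Klrb1c at 223 and 203 in WT and 94.5 and 2060 in the knockout and Blk at 44.0 and 20.3 against 19.5 and 205.

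**Figure D2:**
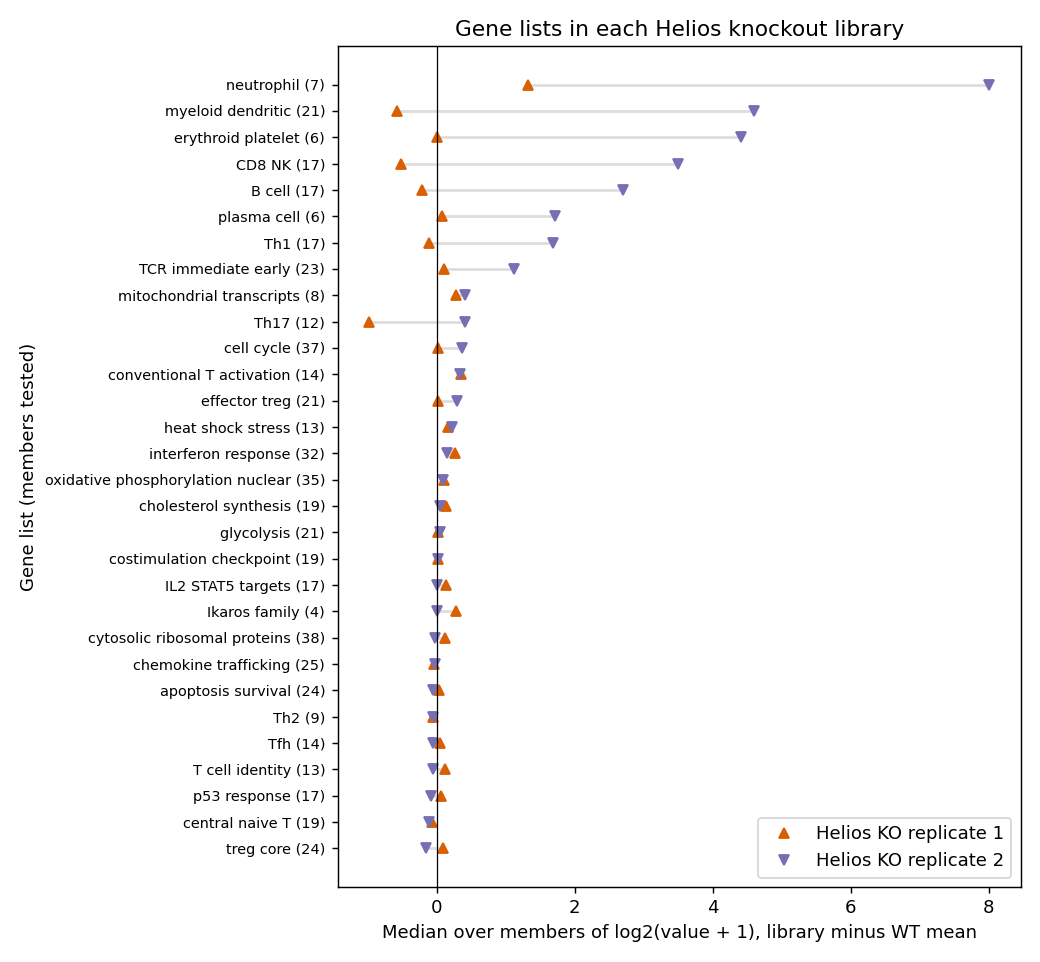
Median over the tested members of each of 30 gene lists of the difference in log2(value + 1) between 1 knockout library and the mean of the WT libraries (x axis), for Helios KO replicate 1 (upward triangles) and replicate 2 (downward triangles). The neutrophil list reaches 8.01 in replicate 2 and 1.33 in replicate 1, while the core Treg list lies at -0.16 and 0.08.

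The libraries of 1 genotype also differed from each other. Reads of Kdm5d, a Y-linked gene of the sex-linked list, numbered 4789 in Helios KO replicate 1 and 0 to 2 in the other libraries. Kdm5d did not pass the low-value filter, so the rule did not name it, and it was taken up after its values were seen. Pearson's r of log2 values across genes, which are not independent replicates, was 0.987 between the WT libraries, 0.984 and 0.985 between Helios KO replicate 1 and the WT libraries, and 0.937 to 0.949 between Helios KO replicate 2 and the others. A leading principal component with 73.5% of the variance set Helios KO replicate 2 apart from the other libraries. Of the 30 lists, 14 were called with the preset correlation, all higher in the knockout, and 0 with an estimated correlation or with fry. Without Helios KO replicate 2, 6 of the 14 were still called higher, 5 were not called and 3 were called lower. Without Helios KO replicate 1, 10 of the 14 were still called higher and 4 were not called, and 11 lists were called in all. Of the 16 lists not called with all libraries, 6 were called without Helios KO replicate 2. These were the Th17 list, lower, and the T cell identity, Ikaros family, interleukin 2 and STAT5, cholesterol synthesis and ribosomal protein lists, higher. In 3262 genes (28.2%) the genotypes did not overlap, where chance gives 33.3%.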

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

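Library quality weights and a fit without the variance trend were chosen after the data were seen, and the other alternatives before. The count of 0 changed genes held under every alternative that kept all 4 libraries, of which the threshold on the log2 fold change could only lower a count. The distance to the threshold varied. The smallest adjusted p in limma was 0.427 in the main fit, 0.0811 with a mean of at least 10 CPM and 0.122 without the variance trend. With no low-value filter it was 0.786. Library quality weights were equal within a group (1.24 in WT and 0.804 in the knockout), so they could not weigh down Helios KO replicate 2 alone. Leaving out antigen receptor, haemoglobin and sex-linked genes kept 11569 of 11571 genes, so it could change little. Leaving out 1 library gave between 0 and 758 changed genes, 0 to 694 higher and 0 to 64 lower, with 0 when a WT library was left out, 40 without Helios KO replicate 2 and 758 without Helios KO replicate 1. The fits without a knockout library draw their spread from the WT libraries alone, which were closer to each other. The fit without Helios KO replicate 1 also rests on Helios KO replicate 2, the library with transcripts of other blood cells. The log2 fold change of Ikzf2 ranged from -1.09 to -0.52 over the libraries left out, and it passed the test only without Helios KO replicate 1 (-1.05).

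Of 30 gene lists, camera called 14, and with an estimated correlation it called 0 and fry called 0. Both allow for members moving together, but with 4 libraries they rest on few degrees of freedom. A call lost there need not reflect members moving together. The conventional T cell activation list had an estimated correlation of -0.026, yet its unadjusted camera p went from 9.44e-07 to 0.0349. The 71 other named genes kept their direction and stayed short of the threshold in each alternative with all 4 libraries in which they were tested, which with a mean of at least 10 CPM was 55 of them. Without Helios KO replicate 1, 26 passed, and without Helios KO replicate 2, 10 passed. The log2 fold change changed sign over the libraries left out for 8 genes that never passed in the fit of all libraries. It ranged from -0.090 to 0.16 for Cd4 and from -0.15 to 0.40 for Ctla4, both negative without Helios KO replicate 1. It ranged from -0.49 to 0.22 for Foxp3, -0.56 to 0.033 for Il2ra and -0.39 to 0.16 for Ikzf4, all positive without Helios KO replicate 2, and from -0.59 to 2.74 for Blk and -1.16 to 3.27 for Klrb1c, both negative without it. For Cyp51 it ranged from -0.00402, without WT replicate 2, to 0.50. The cause of these reversals was not tested.

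With the replicate number as a block, limma called 0 genes, with 335 at an unadjusted p under 0.05, and camera called 17 lists. The correlation of same-numbered deviations was 0.106 over 2 pairs of libraries, and nothing in the labels says that the numbers mark a pair. The planned fits with edgeR and DESeq2 were not run, and limma-voom was the fit made on the recovered reads. Depth limits the genes under the low-value filter, which were tested only in the fit with no low-value filter (0 called), and the libraries held 42090057 or more recovered reads.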

Other observations

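All tests in this part were chosen after the values had been seen, and the genes named here were chosen in the same way unless named above. Each knockout library was also set against both WT libraries alone. Of 11265 genes tested in both fits, 6 were called higher and 9 lower in both, and 8 were called in opposite directions. Independent lists of those sizes would share 0.460 higher and 0.182 lower genes, and simulated unchanged libraries against shared controls gave means of 0.780 and 1.06 and at most 9 in all over 50 draws. Part of the excess may come from the shared WT libraries, which could not be split. The shared genes included Scin, Slc43a1 and Dipk1c (higher) and Actg2, Ptpn5, Ptpn4 and Atp6v0d2 (lower), and also Itga9, an integrin chain, at 1.59 in Helios KO replicate 1 and 2.72 in replicate 2, Npas2, a circadian transcription factor, at -1.77 and -1.27, and Acadl, an enzyme of fatty acid oxidation, at -1.96 and -0.59. Among those that went apart were Anxa1 (-1.99 and 2.67), Il18rap (-1.36 and 1.00) and Lat2 (-2.07 and 1.93). Between the genotypes 19 genes had an unadjusted p under 0.001, and the higher of the 2 other pairings of the 4 libraries had 1. At an unadjusted p under 0.05 the order was the other way, with 386 genes between the genotypes and 417 and 465 in the other pairings, as it was for genes whose groups do not overlap (3262 against 4248 and 4061). At 0.001, 1 of the 3 pairings gave as many genes, and 3 pairings are too few for a share under 0.05.

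Helios KO replicate 2 held transcripts of many blood lineages, such as Apoe (24653 against 1218 to 1709 in the other libraries), Cd74 (40560 against 5701 to 7503), C1qb (7924 against 109 to 354), Ltf (11201 against 15.0 to 57.6), S100a9 (6689 against 0 to 29.2) and Gzma (6114 against 113 to 169). An effect of the genotype shared by both knockout libraries is argued against by Helios KO replicate 1, where the 71 members of the 6 lists had a median difference from WT of -0.22 (quartiles -0.84 and 0.22), against 3.79 (2.14 and 4.87) in replicate 2, and greater depth is argued against by its 48975294 recovered reads, fewer than in either WT library. These members count each gene once and leave out Bst2, which is also in the interferon list. Bst2 was highest in Helios KO replicate 1 (5940 against 5118 in replicate 2). Of the 71 members, 69 (97.2%) were highest in replicate 2. That share restates the pattern and so does not test whether cells or RNA of other lineages were its source. A CD4+CD25+ sort should remove such cells. The 432 tested genes at least 4-fold above all other libraries there held 1.97% of its reads, against 0.137 to 0.171% in the others. No other library had such genes among those tested. The low-value filter drops genes that are high in a single library, such as Kdm5d in Helios KO replicate 1 (1487 against 0 to 0.534 in the others). These counts therefore miss genes of that kind in every library. Cells or RNA of other lineages as the source and an effect of Helios loss that differs between mice both stay open, and the second was not tested.

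Helios KO replicate 1 was the library with reads of the Y-linked gene Kdm5d, with 4789 recovered reads against 0, 1 and 2 in WT replicate 1, WT replicate 2 and Helios KO replicate 2. A candidate explanation is that this sample came from a male mouse and the others from females. Kdm6a, Kdm5c, Eif2s3x and Ddx3x, X-linked genes that escape inactivation, had a median difference of -0.54 between that library and the mean of the others, at percentile 1.51 of 10000 random sets of 4 X-linked genes, and the other X-linked genes had a median of -0.06. Sex would then differ within the knockout group, and differences between that library and the WT libraries could hold effects of sex as well as of genotype. Cdh4 (chromosome 2, 179442431 to 179899373), a cadherin gene, had 43091 and 60923 recovered reads in WT and 50782 in Helios KO replicate 2 but 1 in Helios KO replicate 1.

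Genes with an unadjusted p under 0.01 between the genotypes were more frequent on chromosome 1, which carries Ikzf2, than elsewhere. In all, 94 of 11570 genes had such a p, fewer than chance gives at that threshold, and the other pairings of the libraries had 30 and 47. Of 679 tested genes on chromosome 1, 12 (1.77%) had such a p, against 82 of 10891 (0.753%) elsewhere (two-sided Fisher's exact test, p = 0.0120). That test takes genes as independent, which genes measured in the same libraries are not, and it was not run for the other pairings. A segment of the donor strain linked to the targeted allele may contribute to the higher share, and would place such genes near Ikzf2. Within 20 Mb of it 4 of 166 genes (2.41%) had such a p, namely Gm973 (log2 fold change 2.74), Lancl1 (-0.67), Acsl3 (0.56) and Gpr55 (-0.98), against 8 of 513 (1.56%) on the rest of the chromosome, among them Il1rl1, Il10, Ptpn4 and Npas2 (two-sided Fisher's exact test, p = 0.500), which leaves that explanation open because the genes are few. Regulation of these genes by Helios stays open as well and was not tested.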
